A study of Drosophila melanogaster with 2 samples.

How the data were processed

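The series holds chromatin immunoprecipitation sequencing of cato, an atonal-family basic helix-loop-helix transcription factor, in whole Drosophila melanogaster embryos. Per the labels, embryos of both sexes from a transgenic line carrying cato fused to enhanced green fluorescent protein (eGFP) were collected at 0 to 16 h of development, chromatin was sonicated with a size range of 200 to 800 bp, and the fusion protein was precipitated with an antibody against GFP. There was 1 condition with 2 biological replicates, which the labels number 1 and 3. No second condition and no control library was analysed here.

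The files are peak lists. Per the text lists of files deposited with each library, each replicate has a list of peaks and background made as input for the irreproducible discovery rate (IDR) procedure, and the series has a pooled list and a thresholded list of optimal IDR peaks, each on the genome builds dm6 and dm3. The signal value of each peak is the one the authors deposited, on the scale of their peak caller, and it was used only to rank or describe peaks within a list. The peak caller, its version, the aligner and the read depth are not given in the sources used here, so the depth of each library is unknown and no counting error per peak could be given. The dm6 lists of replicate 1, of replicate 3 and of the pool hold 30000 peaks each, weak ones included. Equal list lengths therefore say nothing of how many sites each library found.

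All positions are on dm6, written 1-based. Genes and transcription start sites came from Ensembl release 115 (BDGP annotation 6.54) and sequence from the RefSeq copy of the same assembly. The dm3 lists served for counts, overlaps and the rank correlation only. Calculations used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.

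Replicates were compared by the share of the 2746 strongest peaks of replicate 1 that overlapped, by at least 1 bp, one of the 2746 strongest of replicate 3, 2746 being the number of IDR peaks. The share was set against 1000 random circular shifts of the peaks within chromosomes, one-sided. The rank correlation used, for each IDR peak, the strongest overlapping peak of each replicate, with 100000 permutations. Summits were classed in the order promoter (within 500 bp of any annotated start site), coding exon, UTR or non-coding exon, intron and intergenic, and compared with 1000 shifts, two-sided. The smallest p that these shifts can give is 0.002.

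The 10 classes of the E-box CANNTG, the sequence bound by basic helix-loop-helix proteins, were counted in the 101 bp window around each summit and in a window 1000 bp away on a side drawn at random. Presence was compared with an exact McNemar test, two-sided, with Benjamini-Hochberg adjustment over the 10 classes and 8 other motifs. All 2080 6-mers were tested in the same windows, with an adjusted p under 0.01 and a ratio of at least 1.5 required. The plan fixed that the side be drawn from a seed but not which seed. Seed 1, the first that was run, is the main draw. A later run with another seed gave a different number of enriched E-box classes, so 20 further draws were made and their spread is given beside the main value. As another control, random positions were matched on location class and on GC content in steps of 5%, and 20 further draws of these were made too. Distance to the start site and side of it were not matched. Ratios with intervals pool 5 matched sets, with a Fisher's exact test added after seeing the data.

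Each IDR peak was given to the protein-coding gene with the nearest start site. For 18 gene lists the share of genes with at least 1 peak was compared with 10000 random lists of the same size matched on decile of territory length, the span of genome nearest to that gene, with a two-sided permutation p adjusted over the lists. The random lists drew genes without regard to position along the chromosome, so neighbouring genes in a list counted as independent. In all, 3 names in the lists were replaced by the annotation's current names after the data had been opened. The lists are proneural and sense organ precursor, Notch pathway and E(spl) complex, chordotonal organ and sensory cilium, neuroblast, differentiated neuron, glia, mesoderm and muscle, endoderm with fat body and haemocyte, trachea, epidermis and cuticle, early embryonic patterning, Hox genes, cell cycle, broadly expressed genes, ribosomal proteins, germline, odorant and gustatory receptors, and yolk and chorion. Named genes are cato, the genes given the 10 IDR peaks of highest signal value, and for each list up to 3 bound members whose best peak has the highest signal value; 1 of these genes is not reported here. The tests, the lists, the rule for named genes and the other settings listed next were fixed before the data were examined. These settings concerned the build, overlap rule, list length, promoter width, window and flank, control positions, gene assignment, the stronger 50% of IDR peaks, and each replicate alone.

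The code was tested on simulated data. An E-box class implanted in 5% of 2746 simulated windows, at equal base composition, was called in 20 of 20 runs. No implant was simulated at the unequal base composition of summits and flanks. With equal base composition and no implant, the mean number of other classes called per run was 0. With no implant but the base composition of summits (32% GC) against that of flanks (43% GC), an average of 4.60 of the 10 classes were called depleted and 222.2 6-mers were called enriched. A list of 25 genes raised to a 50% share was called in 15 of 20 runs, and 1 of 340 unchanged lists was called.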

Results

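The binding of cato, a basic helix-loop-helix factor of the atonal family, was mapped by chromatin immunoprecipitation sequencing in whole embryos of 0 to 16 h. A cato-eGFP fusion protein was precipitated with an antibody against GFP in 2 biological replicates of 1 condition. The thresholded IDR list, made from both replicates, held 2746 peaks on dm6. Of these, 2078 overlapped one of the 2746 strongest peaks in each replicate. The deposited signal values of the IDR peaks ran from 68.9 to 1099.8 with a median of 106.3, and the median width was 404 bp. Read depth is unknown. With a single condition, peaks were compared with the rest of the genome and the replicates with each other.

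Both replicates placed their strong peaks at the same regions. Of the 2746 strongest peaks of replicate 1, 76.4% overlapped one of the 2746 strongest of replicate 3, against a mean of 1.54% and a highest value of 2.55% in 1000 shifts (one-sided permutation p = 0.001, the smallest these shifts can give). Across the 2741 IDR peaks found in both lists, the signal values had a Spearman rho of 0.72 (permutation p = 1e-05, the smallest the permutations can give). The IDR procedure selects peaks on the agreement of ranks, so a positive rho may be partly built in, by an amount that was not tested. Its p is therefore no separate test of agreement. Peaks are also not independent replicates. Among the 20000 strongest peaks of each replicate the overlap was 45.0%, against 10.9% on average in shifts of lists of that length.

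**Figure D1:**
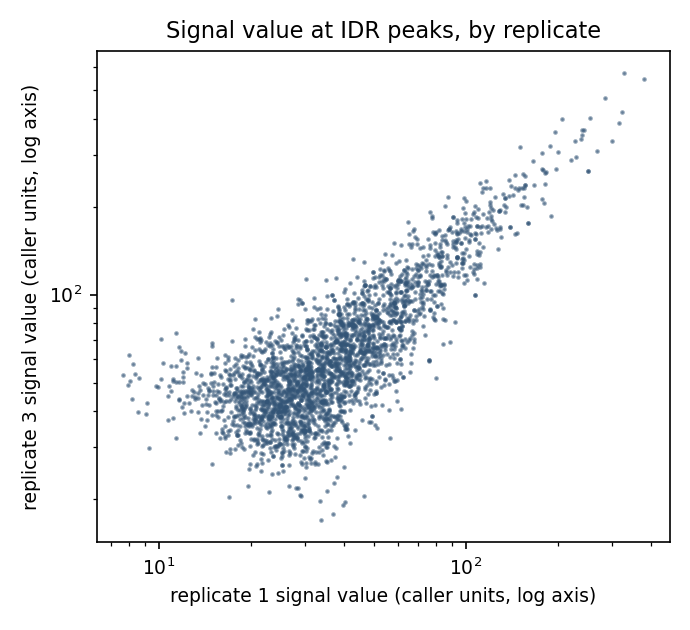
Signal value of the strongest overlapping peak in replicate 1 (x axis) and replicate 3 (y axis), in units of the peak caller on log axes, 1 point per IDR peak. The 2741 points rise together, with a Spearman rho of 0.72.

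Of the 10 strongest peaks, 7 lay at promoters. The highest signal value, 1099.8, belonged to a peak on chromosome 3L from 19590445 to 19590787, whose summit was 86 bp from the start site of CG14100 (FBgn0036889), and this region ranked 1 in replicate 1 and 2 in replicate 3. The next, at 1082.3 on chromosome 2L from 480895 to 481253, was in an intron of ush, which encodes a GATA cofactor, and its nearest start site was that of cbt, 1380 bp away. It ranked 2 in replicate 1 and 1 in replicate 3. Promoter peaks followed at Ugalt, a UDP-galactose transporter gene (signal value 899.6), at px (883.1), at Chro, which encodes the chromatin protein Chromator (853.1), at Tcs5 (757.6), at Art3, an arginine methyltransferase gene (728.5), and at CG8320 (727.7). The other peaks among the 10 strongest were an intergenic one 11919 bp from the start site of CG13323 (788.1) and an intronic one in CG11050 (734.1). In each replicate, all 10 regions ranked 17 or better.

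The bound regions were concentrated at transcription start sites. Summits within 500 bp of a start site numbered 1497 of 2746, or 54.5% (95% Wilson interval 52.6 to 56.4), against 13.5% on average in shifted positions, a ratio of 4.02 (two-sided permutation p = 0.002, the smallest possible). Introns held 31.2% of summits against 39.4% in shifted positions, and intergenic sequence held 12.2% against 27.4%. Only 3 summits, 0.11%, were in coding exons, where shifted positions gave 13.8%. Shifts confined to the span of the IDR peaks, added after seeing the data, gave a mean promoter share of 15.3% (ratio 3.56). Of the 1410 promoter summits close to a protein-coding start site, 88.0% were upstream of it, with a median position of -127 bp. The promoter share was 67.4% in the 549 strongest peaks and 49.9% in the 549 weakest (Fisher's exact test, p = 5.3e-09).

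**Figure D2:**
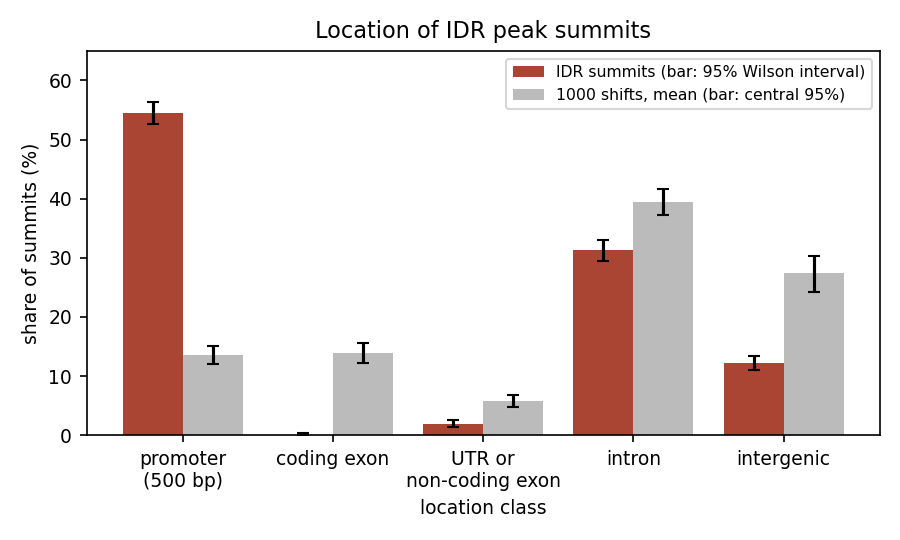
Share of IDR summits in each location class (red, with 95% Wilson interval) and in 1000 circular shifts (grey, mean with the central 95%), in percent. Promoters held 54.5% of summits against 13.5% in the shifts, and coding exons 0.11% against 13.8%.

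No class of E-box, the CANNTG sequence that basic helix-loop-helix proteins bind, passed the test for a higher frequency at summits under every control tried. Against windows 1000 bp away, 7 of the 10 classes were less frequent at summits, among them CACGTG (ratio 0.38, exact McNemar test, adjusted p = 8.9e-04), CACCTG (ratio 0.48, exact McNemar test, adjusted p = 1.0e-05) and CAGCTG (ratio 0.59, exact McNemar test, adjusted p = 4.0e-04). In the main draw of the flank side 1 class, CAAATG, was more frequent, in 10.1% of summit windows and 8.27% of flanks (ratio 1.22, exact McNemar test, adjusted p = 0.027). CAAATG also passed in the stronger 50% of peaks (ratio 1.35, exact McNemar test, adjusted p = 0.026). It did not pass with replicate 3 alone (ratio 1.07, exact McNemar test, adjusted p = 0.51) or replicate 1 alone (1.03, 0.76), and the call depended on the draw: 18 of 20 other draws of the side called 0 classes, with ratios for CAAATG from 1.07 to 1.247. Summit windows had 32.2% GC and the flanks of the main draw 42.9%. Against positions matched on GC content and location class, 0 E-box classes passed in the main draw (exact McNemar test; CAGCTG ratio 1.58, adjusted p = 0.054), and at an unadjusted p under 0.05 CAGCTG alone did. Of 20 other matched draws, 3 called CAGCTG and 1 called CATATG. Over 5 matched sets pooled, CAGCTG passed (ratio 1.40, Fisher's exact test, adjusted p = 0.044) and CATATG had a ratio of 1.30 (Fisher's exact test, adjusted p = 0.051). CATATG also passed with flanks at 500 bp (ratio 1.51, exact McNemar test, adjusted p = 0.0093), with flanks at 2000 bp (ratio 1.41, exact McNemar test, adjusted p = 0.025) and with replicate 3 alone (ratio 1.36, exact McNemar test, adjusted p = 0.039).

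Of 8 other sequences tested, those of DREF and BEAF were more frequent at summits than in both controls. Over 5 matched sets pooled, this held at promoter summits, with ratios of 3.06 for DREF and 2.26 for BEAF (Fisher's exact test, adjusted p = 1.2e-06 and 1.2e-08). At the 1249 other summits neither passed. There DREF was in 2 windows and BEAF in 15 (ratios 0.53 and 0.71, Fisher's exact test, adjusted p = 0.84 and 0.57). The BEAF site was counted as CGATAG, and its bases CGATA can also be part of a DREF site. Windows holding both sites were not set apart, so the DREF and BEAF results may share windows. The DREF site, known from promoters of replication genes, was in 43 summit windows and 7 flank windows (ratio 6.14, exact McNemar test, adjusted p = 1.9e-06), with ratios from 4.78 to 10.75 in 20 other draws and 9.40, on 5 flank windows, with replicate 1 alone. Its ratio was 2.53 against matched positions (exact McNemar test, adjusted p = 0.0096). Matched positions in promoters were not matched on distance to the start site or side of it. What position within promoters contributes to these ratios was not tested. The site of the boundary protein BEAF had ratios of 1.71 (exact McNemar test, adjusted p = 0.0011) and 2.36 (exact McNemar test, adjusted p = 7.7e-06), but did not pass against flanks in the stronger 50% of peaks (ratio 1.5, exact McNemar test, adjusted p = 0.15). The atonal-type E-box, in 12 summit and 17 flank windows, did not pass (ratio 0.71, exact McNemar test, adjusted p = 0.52), nor did it against matched positions (ratio 1.5, exact McNemar test, adjusted p = 0.87, and 0.92 over 5 matched sets pooled, Fisher's exact test, adjusted p = 0.93). The achaete-scute-type E-box (ratio 0.41, exact McNemar test, adjusted p = 4.0e-04), the GAGA site (0.41, 4.0e-04, ratio 0.25 with replicate 1 alone) and the CA repeat (0.23, 4.1e-10, ratio 0.39 with replicate 3 alone) were less frequent than in flanks. Over the pooled matched sets the CA repeat still was (ratio 0.56, Fisher's exact test, adjusted p = 0.044), while the ratios of the achaete-scute-type E-box and GAGA were 1.28 and 1.52 (Fisher's exact test, adjusted p = 0.68 and 0.20). The Zelda and Grainyhead sites passed neither test in the main settings, though Zelda was less frequent than in flanks at 2000 bp (ratio 0.35, exact McNemar test, adjusted p = 0.0090) and with replicate 1 alone (0.39, 0.033). Of all 6-mers, 255 were at least 1.5 times as frequent at summits as in flanks, 36 of them made of A and T alone. Against matched positions 16 passed, none of them of A and T alone. The planned test by peak strength took the E-box class of largest ratio in the main draw, CAAATG. It had the largest ratio in 7 of 20 other flank draws and 0 of 20 matched draws. CAAATG was in 10.4% of the 549 strongest peaks and 9.47% of the 549 weakest, a difference of 0.91 percentage points (Fisher's exact test, p = 0.69). CAGCTG was in 1.64% and 3.28% (Fisher's exact test, p = 0.12) and any E-box in 31.9% and 34.6% (Fisher's exact test, p = 0.37).

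**Figure D3:**
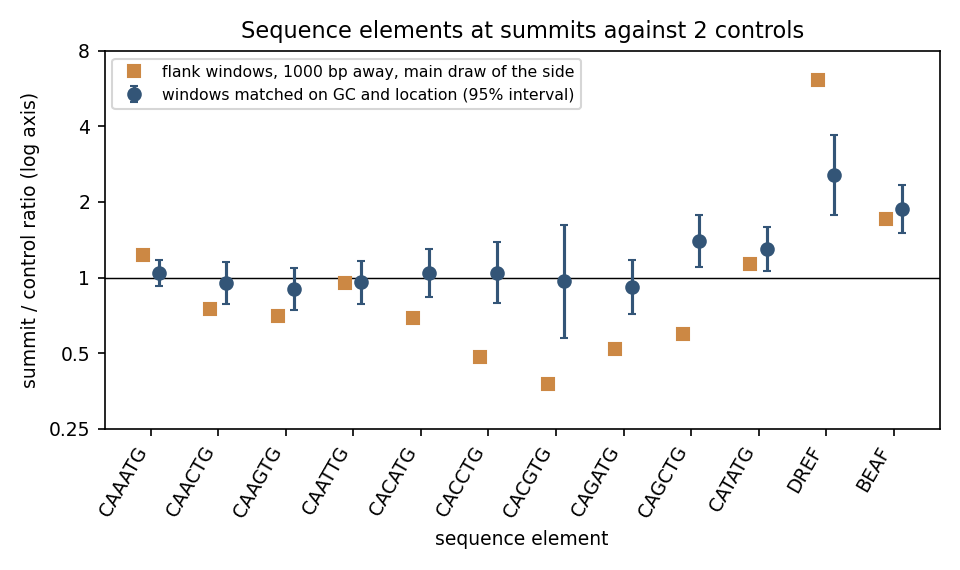
Ratio of the share of summit windows holding each element to the share of control windows, on a log axis. Squares are flank windows of the main draw and circles windows matched on GC content and location, with 95% intervals. CACGTG lies at 0.38 against flanks and 0.97 against matched windows.

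The peaks fell near 2119 of 13945 protein-coding genes, 15.2%, and 2 of 18 gene lists were bound more often than matched random lists. Ribosomal protein genes had a peak in 42 of 86 cases, 48.8%, against 12.6% in random lists (permutation test, adjusted p = 0.0018). The strongest were at RpS27 (signal value 326.8, summit 15 bp from the start site) and RpL7 (291.9, 41 bp). Broadly expressed genes had a peak in 6 of 13 cases, 46.2%, against 12.9% (permutation test, adjusted p = 0.040). Among them were the glycolytic gene Gapdh2 (319.2), the actin gene Act5C (164.6) and the chaperone gene Hsp83 (130.0). The call for broadly expressed genes was lost when only peaks within 500 bp of a start site of the gene were used (permutation test, adjusted p = 0.072), when genes named by a CG number were left out (0.092), with peaks in gene bodies or within 1 kb (0.064) and with the dm6 pooled list (0.17). The bound share in these settings was 46.2%, 46.2%, 53.8% and 38.5%.

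Odorant and gustatory receptor genes, which serve adult and larval chemosensation, were bound less often than random lists. Peaks fell to 3 of 119, 2.52%, against 15.1% (permutation test, adjusted p = 0.0018). These were Gr93a (139.2), Gr89a (134.0) and Gr93d (82.3), all from intergenic summits.

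Lists tied to the known role of atonal-family factors in sense organs did not pass the test. Of 21 proneural and sense organ precursor genes, 8 had a peak, 38.1% against 21.1% in random lists (permutation test, adjusted p = 0.22). The strongest were at edl, with 4 peaks and a best signal value of 319.4 in an intron on chromosome 2R from 18671634 to 18671830, at numb, a cell fate determinant of asymmetric division (223.0, promoter), and at ct (134.3, intron). This list passed with replicate 1 alone, at 10 of 21 genes (permutation test, adjusted p = 0.048), and, like the glial and cell cycle lists, without matching on territory length (permutation test, adjusted p = 0.049). Of 25 Notch pathway and E(spl) complex genes, 8 had a peak (permutation test, adjusted p = 0.22), led by E(spl)m3-HLH (263.3), the co-repressor gene gro (263.0) and E(spl)m2-BFM (149.6). These 3 genes are neighbours, all between 26016514 and 26049911 on chromosome 3R, which the random lists do not take into account. Of 28 chordotonal organ and sensory cilium genes, 2 had a peak, 7.14% against 16.6% (permutation test, adjusted p = 0.41): Kap3 (72.3) and IFT57 (71.2), both close to the lowest signal value of the list. With replicate 3 alone the count was 1 of 28, and IFT57 had no peak among the 2746 strongest of either replicate.

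None of the remaining lists, most of them for other cell types, passed. In the nervous system, 3 of 25 neuroblast genes (brat, grh and mid), 2 of 24 differentiated neuron genes (elav at 342.3 and Syx1A at 91.1) and 6 of 13 glial genes (led by moody, pnt and Gs2) had a peak, with adjusted permutation p of 0.34, 0.22 and 0.12. The neuroblast count was 6 of 25 with replicate 3 alone (adjusted permutation p = 1). Peaks were given to 6 of 24 mesoderm and muscle genes (kirre, sls and tin the strongest, adjusted permutation p = 0.89), and to 4 of 12 endoderm, fat body and haemocyte genes (zfh1, ush and fkh, adjusted permutation p = 0.72). The tracheal list had 5 of 13 (rib, trh and salm, adjusted permutation p = 0.57) and the epidermal list 4 of 14 (grh, sn and ovo, adjusted permutation p = 0.89). Early patterning genes had 14 of 36, led by slp2 (264.8), brk (219.2) and sog (137.4), with an adjusted permutation p of 0.19 (0.0036 without matching on territory length). The list named Hox genes, which also holds hth, not itself a Hox gene, had 3 of 10 (Abd-B, hth and Antp, adjusted permutation p = 1). Cell cycle genes had 7 of 17 (CycB at 405.5, CycE and Dp, adjusted permutation p = 0.076). The germline list had 1 of 12, piwi (adjusted permutation p = 1), and yolk and chorion genes 0 of 12 (adjusted permutation p = 0.57). With replicate 3 alone the germline count was 2 of 12, without piwi. A replicate 3 peak overlapping the piwi promoter peak still ranked 1826 in that list.

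**Figure D4:**
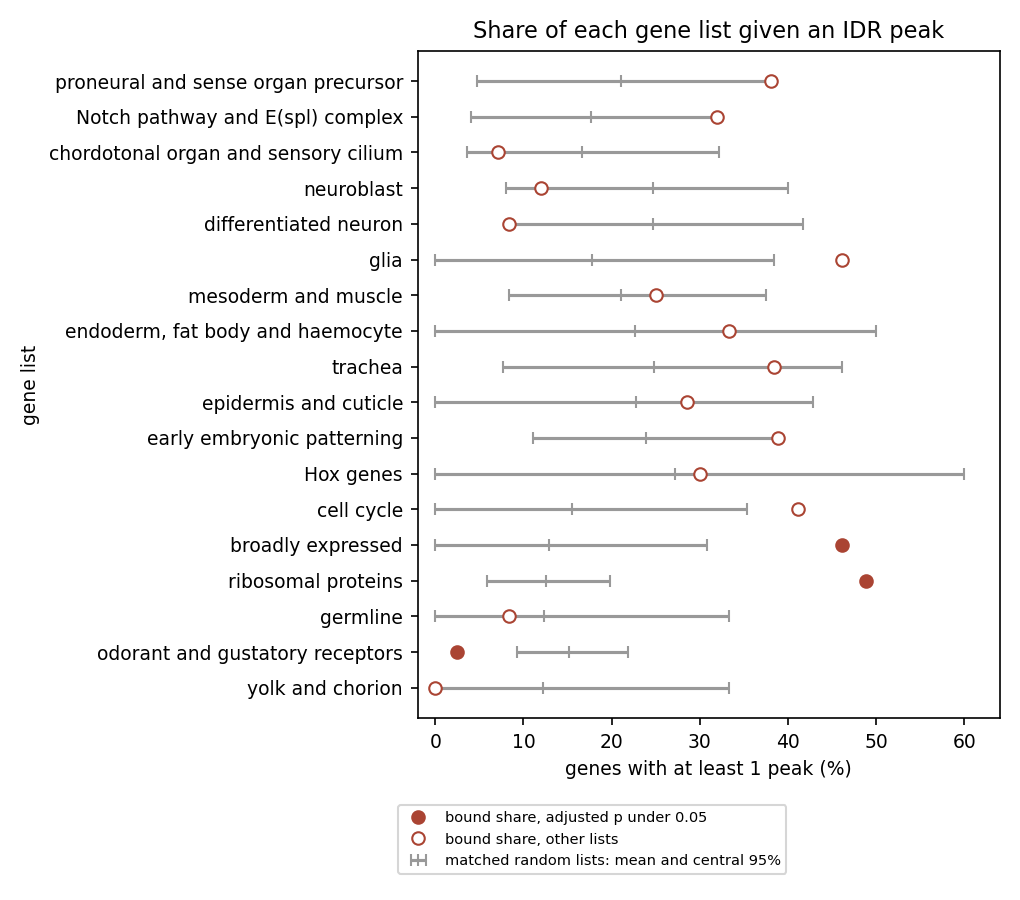
Share of genes in each list with at least 1 IDR peak, in percent (circles, filled where the adjusted p was under 0.05), beside the mean and central 95% of 10000 random lists matched on territory length (grey). Ribosomal proteins, at 48.8%, lie beyond the upper end of their random lists, 19.8%.

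The cato gene itself (FBgn0024249, chromosome 2R from 16277685 to 16278396, minus strand) had no IDR peak within 5000 bp, and the nearest was 16274 bp from the middle of the gene. In the full lists of replicate 1 and replicate 3, 4 peaks each fell in that region, with signal values up to 17 and 31, at rank 4260 and rank 3489 of 30000. No peak of replicate 1 in that region overlapped one of replicate 3. The strongest ran from 16280299 to 16280678 in replicate 1 and from 16279487 to 16279896 in replicate 3.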

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

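The tests in this part were chosen after the results they bear on had been seen. The dm6 pooled list, which entered only settings added after seeing the data, overlapped 96.2% of the dm6 IDR peaks. The dm3 lists, used for counts, overlaps and the rank correlation only, held 274 peaks on heterochromatin and unplaced scaffolds in replicate 1. In replicate 3 they held 159.

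The dm6 pooled list differs from what its description would give. On dm3 all 2655 IDR peaks are rows of the pooled list, and on dm6 0 of 2746, or 0%, are, which argues against its being the pool from which the IDR list was taken. Of its 500 strongest peaks at least 99.6% overlap a peak of each replicate. Among its 2746 strongest only 83.8% overlap the full list of replicate 1 and 86.9% that of replicate 3, with 251 in neither. By the same measure, 99.3% of the 2746 strongest peaks of replicate 1 overlap the full list of replicate 3. The reverse share is 98.5%. A shallower sampling of the same sites and another library with the same strong sites both stay open.

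Summits are AT-rich and hold fewer E-boxes than their flanks. In windows matched on GC content and location, the share with any E-box gave a summit to control ratio of 1.03, so the deficit is consistent with base composition. The excess of summit windows with an E-box over matched windows was 0.83 percentage points, which argues against E-boxes under most summits as the basis of the peaks. Binding through an E-box at a minority of summits stays open.

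Peaks are enriched near ribosomal protein and broadly expressed genes. Short distances between start sites would place ribosomal genes within matched random lists, but those averaged 12.6% bound against 48.8%. Signal at active promoters whatever the tagged protein cannot be told apart from binding of the fusion protein, because no immunoprecipitation from an untagged line was analysed here; the E-box ratio at promoter summits against matched promoters was 0.93. Occupancy at sense organ genes also stays open: the proneural list missed the threshold (permutation test, adjusted p = 0.22), which does not exclude it.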

How the results depend on the processing

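The settings that use the dm6 pooled list, other draws of the flank side or of matched positions, or shifts within the span of the peaks were chosen after seeing the data. Replicate overlap, rank correlation and promoter share kept their direction and side of the threshold in every setting run for them. The IDR peak count, which has no test, was 2655 on dm3. Leaving out a replicate could not be applied to the count, the overlap or the correlation. No paired analysis was possible because there is 1 group. The number of enriched E-box classes fell from 1 to 0 with 51 bp windows, with the widest windows and with matched random positions, was 0 at the lowest in other draws of the flank side and of matched positions, and ran from 0 to 1 with 1 replicate left out. The number of enriched 6-mers, 255, became 16 with matched random positions (8 to 18 in other draws of these) and 115 with the dm6 pooled list. Matched positions changed GC content, location class and placement together. In simulated windows with the base composition of summits and flanks and no implant, an average of 222.2 6-mers were called enriched. Base composition alone can thus give a 6-mer count of this size, but its part in these changes was not measured. The difference in CAAATG between strong and weak peaks, 0.91 points, was -1.82 with the widest windows, -1.09 in the stronger 50% of peaks, -0.36 with the dm6 pooled list and -0.73 with either replicate left out, and passed no threshold. The number of enriched gene lists, 2, became 1 with gene bodies or 1 kb, with start sites of the gene within 500 bp, without genes named by a CG number and with the dm6 pooled list, and 6 with no matching on territory length; the cause was not tested.

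Other values changed direction, and of these CAATTG passed the threshold with the dm6 pooled list and CAGCTG in 3 of 20 other matched draws and over 5 matched sets pooled. With matched random positions the ratios were CAAATG 0.95, CAAGTG 1.05, CAATTG 1.02, CACATG 1.02, CACCTG 1.35 and CAGCTG 1.58. CAAATG was 0.97 with flanks at 500 bp. CAATTG was 1.11 with flanks at 2000 bp, 1.51 with the dm6 pooled list (exact McNemar test, adjusted p = 0.015) and 1.118 to 1.123 with 1 replicate left out, and CATATG fell to 1 in the stronger 50% of peaks. With start sites of the gene within 500 bp, the bound share was 8.33% for endoderm, 0% for epidermis, 5.56% for early patterning, 0% for Hox genes and 25% for germline. With gene bodies or 1 kb it was 23.1% for trachea, 21.4% for epidermis, 19.4% for early patterning and 25% for germline. Without genes named by a CG number it was 25% for mesoderm and 30% for Hox genes. The germline share was 8.33% in the stronger 50% of peaks and 16.7% without replicate 1; without replicate 3 it was 8.33% and kept its direction. Of 56 named genes, 54 and 55 had a peak with replicate 1 and replicate 3 left out, and 31 when a start site of the gene within 500 bp was required. Read depth is unknown, so what it limits could not be measured.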

Other observations

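The held-out tests of 2 sequences in this part had their outcomes stated beforehand; the sequences themselves, and all other tests here, were chosen after the data had been seen. Several genes collected many peaks. The genes shn, tara, Raf and CG43245 had 8 each, and ush, sbb, Hr4 and CHES-1-like had 7 each. Raf did so with a territory of 21.2 kb, against 52.2 kb for CG43245. Chromosome 4 had 6 IDR peaks, or 4.45 per Mb (95% Poisson interval 1.63 to 9.69), and chromosome 2L 22.3 per Mb (20.5 to 24.3). These intervals treat peaks as independent. In the full lists of replicate 1 and replicate 3, chromosome 4 (1.35 Mb) held 281 and 457 peaks. Chromosome 2L (23.5 Mb) held 6020 and 5812, so the low density on chromosome 4 is that of the thresholded list.

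Some DNA words were more frequent at IDR summits than in windows matched on GC content and location. ACAGTG was in 195 windows, a ratio of 2.29, and the consensus AGRTGGCGC, which resembles the site of the boundary protein CTCF, in 25 windows. These words were picked from the same windows, so no p is given for them there. They were then counted at 3238 other summits, among the 5000 strongest peaks of each replicate and over 1000 bp from any IDR summit. There ACAGTG had a ratio of 2.02 (95% interval 1.75 to 2.33) and the CTCF-type consensus a ratio of 7.78 (4.31 to 14.04). Which protein occupies these sites was not tested.

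The E-box class CAGCTG was more frequent at summits over 5 matched sets, with a ratio of 1.40 (95% interval 1.10 to 1.78), while single draws passed the threshold in 3 of 20 cases. The interval for CATATG was 1.06 to 1.59. Its ratio was 1.58 (1.18 to 2.10) at summits outside promoters and 1.09 (0.82 to 1.46) at promoter summits. At the 3238 other summits the ratio was 1.38 (1.13 to 1.67) for CAGCTG and 1.14 (0.93 to 1.39) for CATATG, with no outcome stated beforehand. Any E-box had a ratio of 1.07 (1.02 to 1.13) at those summits, also with no outcome stated beforehand.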
